A study of Mus musculus with 12 samples.

How the data were processed

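RNA of CD8+ T cells from spleen and lymph nodes of wild-type male mice was measured by bulk RNA sequencing in 12 libraries, 3 of each group: naive cells of day 0, and activated cells kept until day 4 in media, bovine collagen gel or rat tail collagen gel. Per the labels, RNA was treated with DNase, 150 ng went into each library and ribosomal RNA was depleted before library preparation. The submitters' processing notes name FastQC, MultiQC, HISAT2, SAMtools, Picard and featureCounts and the builds GRCm38 and mm10. Versions, strand setting and the annotation release are not given in the sources used here. The authors deposited 1 table of raw read counts with 55291 gene symbols and a column per library, and its values are whole numbers that were taken as counts without any change. Columns were joined to groups through the library names in the table header and the sample labels. Totals per library ran from 28483064 to 53138362 counts. The labels state n = 3 per group and give the groups the same replicate numbers, and they do not say whether a number marks the same mouse. The p-values therefore measure the spread between these libraries.

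Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Genes were kept by filterByExpr with the group, libraries were scaled with TMM factors, and each gene was tested with the quasi-likelihood F test of edgeR with robust estimation. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and an adjusted p under 0.05 made a call. The 9 day 4 libraries shared 1 fit for rat tail collagen against media, bovine collagen against media and rat tail against bovine collagen (19392 genes). Media against naive was fitted on the 6 libraries of these groups (18610 genes). The common biological coefficient of variation was 12.2% in the day 4 fit and 13.5% in the other. Levels in CPM use 1 TMM scale over the 12 libraries. Principal components used log2 CPM of the 500 most variable genes with a prior count of 2. The overlap of both collagen comparisons was set against independent lists and against 20 simulated sets of unchanged groups that shared the media libraries. A group total of 3 counts served as the floor for genes without counts in a group, and intervals of count ratios were exact at 95%.

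Gene lists, 32 in number, were written from general knowledge of T cell biology. Lists with 5 or more genes past the filter were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other genes. Fry tests whether a list's genes move on balance one way, and does not compare them with other genes. Counts of list members are given over all genes tested and adjusted over the list alone. Named genes were the 8 largest changes in each direction per comparison with an adjusted p under 0.05, all 3 libraries of one group on one side of the other group's, a mean of 5 CPM or more in the higher group and a symbol that is not a clone or predicted name. To these came up to 4 members per list with the smallest adjusted p, of which the text gives at least 2, and 13 genes of residence, homing and effector function in every comparison, 12 of which are given. The results of some genes these rules name are not reported here. The comparisons, tests, lists, naming rule and first set of alternatives were made before the data were examined. Klf4, Gm37352, Cd24a and the genes of the response to tonicity were chosen after their values were seen. Locations and overlaps come from GENCODE M21 on GRCm38, in which 53291 of the symbols were found, and the symbols not found held 2.28% of counts.

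The alternatives tried were RLE factors, library totals, DESeq2, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, all 12 libraries in one fit, only the 6 libraries of a comparison, replicate number as a block, estimation without robustness, a 2-fold minimum and leaving out each library in turn. For lists the alternatives were an estimated correlation, fry, RLE factors, the CPM filter, the block and leaving out each library. Further alternatives were added after the data were seen: removal of rRNA genes, leaving out the 3 libraries with the highest share of rRNA (bovine collagen 2 and rat tail collagen 1 and 3), and offsets for each library's trend with GC content and transcript length, which were known for 97.4% of the genes tested. Reads were not analysed here, so duplicates, strand and mapping rates were not checked.

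The pipeline was tested on simulated data, drawn from the means, library sizes and dispersions of each comparison, with known changes in 200 genes. Of genes changed 4-fold, 2-fold and 1.5-fold, it recovered 89.4%, 64.2% and 38.8% in rat tail collagen against media, 93.9%, 65.7% and 49.3% in bovine collagen against media, 95.5%, 65.7% and 47.8% in rat tail against bovine collagen, and 89.4%, 64.2% and 52.2% in media against naive. Unchanged genes made up 5.19%, 4.79%, 4.79% and 11.04% of the calls in the same order of comparisons. The share was thus slightly above the 5% aimed at in rat tail collagen against media and further above it in media against naive. No recovered gene had the wrong sign. Each comparison was simulated once, with 200 of 18240 to 18968 genes changed. In the data 58.4% of genes were called in rat tail collagen against media, 54.7% in rat tail against bovine collagen and 60.8% in media against naive. Recovery and the share of unchanged genes in those comparisons are therefore not described by this test.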

Results

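Bulk RNA sequencing after ribosomal RNA depletion measured transcript levels in mouse CD8+ T cells from spleen and lymph nodes. There were 4 groups of 3 libraries. Naive cells were lysed fresh on day 0. The other cells were activated for 2 days through CD3 and CD28, expanded for 1 day in interleukin 2, and moved on day 3 for 24 h into liquid media or into a gel of bovine collagen or of rat tail collagen, each at 2 mg/mL. Their RNA was taken on day 4. The deposited table held raw read counts for 55291 gene symbols, and totals per library ran from 28483064 (bovine collagen 2) to 53138362 (media 1). Levels are given in CPM, counts scaled to library size with TMM factors, as mean ± SD of n = 3 libraries, changes are log2 fold changes from edgeR, and adjusted p-values cover all genes tested. Floors and intervals cover counting error only, since the reads carry no stated molecular identifiers. The counting floor was 3 counts over a group.

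Some signs of RNA composition moved with the groups. Genes of ribosomal RNA took 10.96%, 5.03% and 13.2% of counts in rat tail collagen 1, 2 and 3 and 6.41%, 11.9% and 5.50% in bovine collagen, against 4.57 ± 0.137% in media and 5.06 ± 0.958% in naive cells. Malat1, an abundant nuclear long noncoding RNA, took 1.34 ± 0.197% of counts in rat tail collagen, 0.256 ± 0.0667% in media, 0.226 ± 0.0439% in bovine collagen and 0.791 ± 0.0986% in naive cells. All lincRNA genes together, Malat1 included, took 1.97 ± 0.227% in rat tail collagen against 0.867 ± 0.113% in media. Malat1 made up nearly all of this difference, so these shares show no broad rise of other lincRNA genes. Mitochondrial transcripts took 2.10 ± 0.358% in rat tail collagen and 1.47 ± 0.149% in media. Counts were seen for 28874 ± 1088 symbols in rat tail collagen, 28662 ± 1344 in naive cells, 26188 ± 78.9 in media and 25086 ± 655 in bovine collagen. The first principal component held 62.2% of the variance of the 500 most variable genes. On it naive libraries lay from -69.6 to -69.0, media and bovine collagen libraries together from 8.85 to 13.6 and rat tail collagen libraries from 46.2 to 48.1. The second held 33.9%. There naive libraries (16.9 to 22.4) lay on the same side as rat tail collagen (39.6 to 45.5), opposite to media and bovine collagen (-31.9 to -27.2).

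**Figure D1:**
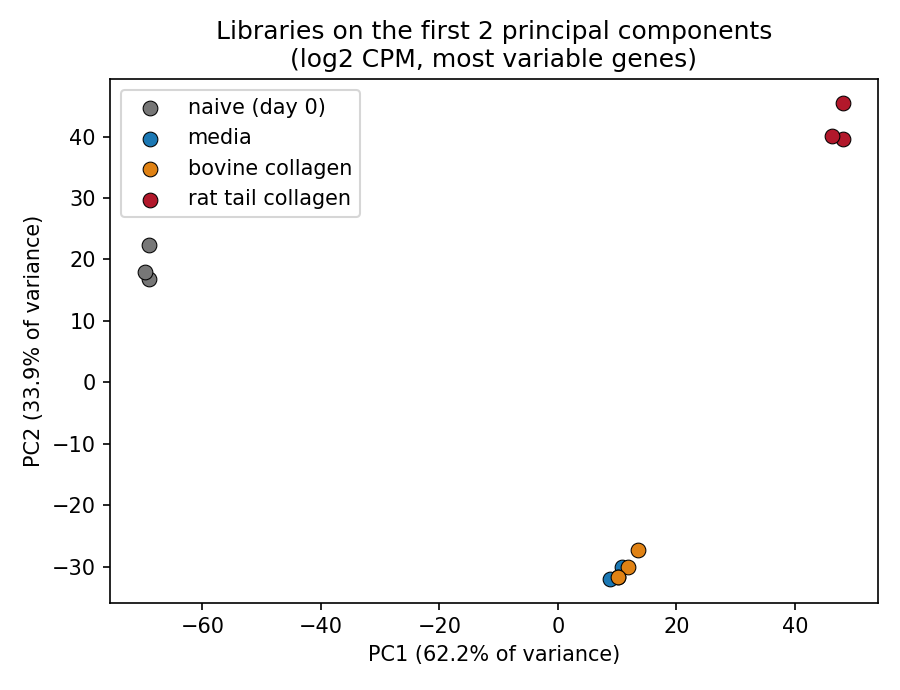
Principal components of log2 CPM of the 500 most variable genes, with PC1 (62.2% of variance) on the horizontal and PC2 (33.9%) on the vertical axis and a point per library. Naive libraries lie left of -69 on PC1, the media and bovine collagen libraries share one region, and the rat tail collagen libraries lie right of 46. On PC2 the naive and rat tail collagen libraries lie on the positive side and the media and bovine collagen libraries on the negative side.

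Rat tail collagen was compared with media to show what a day in that gel goes with in activated CD8+ T cells, in a series whose title concerns mechanosensing and the tissue-resident memory program. The chemokine receptor gene Ccr2 (GRCm38 chromosome 9, 124101950 to 124113557) fell 50.1-fold, from 162 ± 17.6 CPM in media to 3.21 ± 0.609 in rat tail collagen (log2 -5.65, adjusted p = 6.09e-10). Slc6a12, the betaine and GABA transporter (chromosome 6, 121343076 to 121365775), rose from 0.0358 ± 0.0347 to 109 ± 28.0 CPM (log2 11.47, adjusted p = 1.46e-09). Stc1, which encodes the secreted glycoprotein stanniocalcin (chromosome 14, 69029238 to 69041804), rose from 0.0617 ± 0.0337 to 117 ± 6.76 CPM (log2 10.79).

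Further genes were near 0 in media and expressed in rat tail collagen. Tnn, a tenascin of the extracellular matrix (chromosome 1, 160085029 to 160153580), had no counts in media and 15.1 ± 4.90 CPM in rat tail collagen, at least 733-fold higher. The sulfotransferase gene Chst1 had a ratio of 1594 (441 to 13166), Accsl of 1248 (427 to 6057) and Prrg3 of 1481 (265 to 58540.0), with counting intervals at 95% in parentheses. Npr1, a natriuretic peptide receptor, rose by log2 9.87 to 29.3 ± 6.01 CPM, and the teneurin gene Tenm4 by 9.16 to 34.0 ± 3.57 CPM. Among the largest falls were 3 interferon-inducible genes of the HIN-200 cluster on chromosome 1, Ifi213 at -5.50, Ifi208 at -4.51 and Ifi206 at -4.49. The copies of this cluster are similar in sequence, so the values of single members are uncertain. Cd7, a T cell surface protein gene, fell from 45.0 ± 13.1 to 1.62 ± 0.437 CPM (-4.78). Rap1gap2, an inactivator of the GTPase Rap1, also fell (-4.31), as did the interferon-induced Rtp4 (-4.31). In the annotation Stc1, Npr1, Tenm4 and Cd7 overlap a gene on the other strand, and Rtp4 overlaps one on its own strand.

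Genes known to be lower in resident memory T cells fell together: 15 of 19 measured members fell and 0 rose, with a median of -1.79. Klf2, a regulator of T cell egress, fell from 143 ± 22.9 to 26.8 ± 14.3 CPM (-2.43), S1pr1, the receptor for egress from lymph nodes, from 309 ± 16.4 to 92.3 ± 8.31 (-1.75), and Ripor2 was at -2.55. Camera gave this list an adjusted p of 4.47e-19, and the adjusted p was 0.0261 with an estimated correlation. Members of the list known to be higher in resident memory cells went both ways: 18 of 31 rose, 9 fell, and the list did not pass (adjusted p = 0.129). Cdh1, which encodes E-cadherin, rose to 10.9 ± 3.02 CPM (5.12), and so did Nr4a2 (2.17), a nuclear receptor induced by antigen receptor signals. Itga1, the integrin CD49a that binds collagen, rose from 0.787 ± 0.0781 to 2.98 ± 0.823 CPM (1.91). Members that fell were Itgae, the integrin CD103, from 227 ± 77.2 to 73.2 ± 18.8 CPM (-1.64), Cd69 (-0.97), the chemokine receptor gene Cxcr6 (-2.52) and Zfp683, which encodes the transcription factor Hobit (-1.49). Chemokine and S1P receptor genes fell in 10 of 14 and rose in 3. Among them Gpr183 was at -3.52 and S1pr4 at -2.14 (list median -1.18, adjusted p = 1.16e-09, and adjusted p = 0.0138 with an estimated correlation). Of the naive and stem-like genes 11 of 20 fell, with Il7r at -1.46 and Lef1 at -1.61 (adjusted p = 3.32e-05, and adjusted p = 0.315 with an estimated correlation). Ccr7 was at -0.19 (adjusted p = 0.183) and Tcf7 at -0.13 (adjusted p = 0.413), and neither passed the test, though Ccr7 passed with no filter (-0.24, adjusted p = 0.0308), without rat tail collagen 3 (-0.31, 0.0343) and with GC and length offsets (-0.33, 0.0234).

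**Figure D2:**
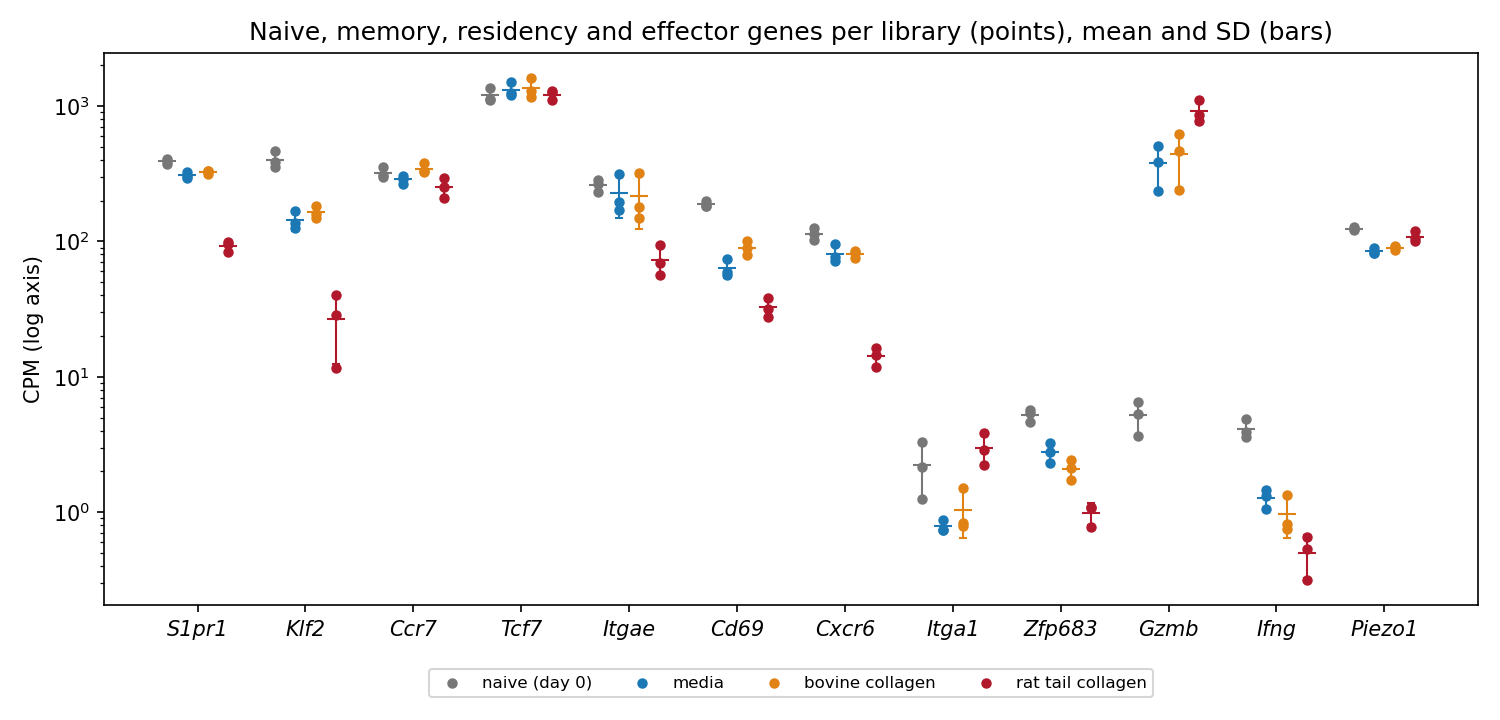
Levels of 12 genes of T cell residence, homing and effector function in CPM on a log axis, with a point per library and the mean and SD of n = 3 for each of the 4 groups. Klf2 lay at 26.8 ± 14.3 CPM in rat tail collagen and at 143 ± 22.9 in media, and Itga1 at 2.98 ± 0.823 and 0.787 ± 0.0781.

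Cell cycle genes fell. All 30 measured genes of G2 and mitosis fell, with a median of -1.10, among them the mitotic regulators Cdc20 (-1.26) and Birc5 (-1.46). Of the S phase genes 25 of 31 fell and 0 rose, among them Rrm2 (-1.43) and Tyms (-1.11), both of nucleotide supply. The adjusted p of these lists was 7.29e-18 and 3.08e-07, and the adjusted p was 0.306 and 0.355 with an estimated correlation. The actin and motility list had 26 of 31 members lower and 4 higher. Its largest fall was in Vim, the intermediate filament protein vimentin, from 1226 ± 120.4 to 212 ± 60.2 CPM, Coro1a was at -1.19, and the GTPase gene Rhob rose by 2.11 (adjusted p = 4.69e-04, and adjusted p = 0.306 with an estimated correlation). The lists of mechanics that follow did not pass with camera. Fry called the mechanosensitive channels and the YAP and TAZ targets higher (adjusted p = 0.00717 and 0.00108). It did not call the SRF and MRTF targets or the integrins (adjusted p = 0.207 and 0.0614). In the mechanosensitive channel list 4 of 9 rose and 3 fell, with Trpv4 at 2.51, Tmem63b at 1.44 and Piezo1 at 0.35 (84.2 ± 4.10 to 108 ± 10.5 CPM). Of the YAP and TAZ targets 6 of 13 rose, such as Arhgef17 (3.35) and Dock5 (2.80), and 3 fell. Of the SRF and MRTF targets 5 of 15 rose, led by the actin oxidase gene Mical2 (4.59), and 7 fell, such as Flna (-1.02). Integrins and matrix receptors rose in 7 and fell in 5 of 15, with the collagen-binding Itga2 at -3.60, the collagen receptors Lair1 at -2.55 and Ddr1 at 1.83.

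Stress genes rose in part. Of the heat shock genes 8 of 14 rose and 3 fell. Hspa1b reached 76.4 ± 12.5 CPM from 0.758 ± 0.117, Hspa1a changed by 6.90, and Hsph1 by 3.48 (adjusted p = 2.05e-07, and adjusted p = 0.286 with an estimated correlation). The HSP70 genes Hspa1a and Hspa1b are near-identical, so their separate values are uncertain. In the TGF-beta list 7 of 12 rose, among them Skil (1.52) and Pmepa1 (2.23), while its member Itgae fell (adjusted p = 0.0421, and adjusted p = 0.504 with an estimated correlation). Without any one of 4 libraries this list did not pass: the adjusted p was 0.0527 without media 1, 0.0705 without media 2, 0.0626 without rat tail collagen 2 and 0.0790 without rat tail collagen 3. Type I interferon genes fell in 17 of 26 and rose in 3, with the transcription factor gene Irf7 at -1.97 and Cmpk2 at -2.35 (adjusted p = 5.84e-04, and adjusted p = 0.504 with an estimated correlation). Effector genes rose in 6 and fell in 10 of 22: Gzmb, which encodes the protease granzyme B, rose from 376 ± 135 to 913 ± 179 CPM (1.27), Ifng fell from 1.28 ± 0.199 to 0.503 ± 0.174 (-1.34), and Tnf (-0.87) and Nkg7 (-0.78) fell. Inhibitory receptor genes rose in 6 and fell in 3 of 13, with Entpd1 at 1.96 and Cd160 at -2.49.

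The other signalling lists did not pass with camera. T cell receptor response genes rose in 5 and fell in 10 of 19, with the costimulatory receptor gene Tnfrsf4 at 2.81 and Irf4 at -0.78. Immediate early genes rose in 11 and fell in 6 of 22, with Ier3 at 1.85 and Zfp36 at -1.84. IL-2 and STAT5 genes rose in 6 and fell in 4 of 13, with Socs3 at 1.24 and Ccnd3 at -0.77. In the NF-kB list 4 of 16 rose and 5 fell, with Cd83 at 2.11 and Rel at -1.21. The p53 targets rose in 11 and fell in 4 of 18, with the cell cycle inhibitor gene Cdkn1a at 1.69 and Aen at 1.05. Targets of the amino acid response rose in 10 of 20, with Chac1 at 2.46 and Atf5 at 1.03. The unfolded protein response had 5 higher and 4 lower of 16, with Xbp1 at 1.23 and Dnajc3 at -0.76. Hypoxia genes fell in 13 and rose in 3 of 24, with Pdk1 at -2.33 and Pfkfb4 at 2.12. In the glycolysis list 7 of 17 fell and 3 rose, with Gpi1 at -0.84 and Slc16a1 at -0.83. Oxidative phosphorylation genes fell in 11 of 31, with Atp5c1 at -0.70 and Uqcrfs1 at -0.56. Cholesterol synthesis genes fell in 12 and rose in 4 of 24, with Ebp at -0.83 and Insig1 at -1.33.

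Markers of other cells went both ways. Of the stromal markers Col1a1, a collagen chain, rose from 0.311 ± 0.0504 to 4.29 ± 0.535 CPM and Fn1 from 0.161 ± 0.0280 to 1.71 ± 0.308, and Pecam1 was at -0.97. Among myeloid markers 4 of 7 rose and 2 fell, with Cd14 at 0.902 ± 0.158 CPM (3.25) and the lysosomal Cd68 at 1.58. In the NK, gamma-delta and CD4 T cell list Klrb1c rose to 8.70 ± 1.09 CPM (4.71) and Zbtb7b by 1.04, and 6 of 11 did not pass. Of the 4 measured B cell markers 1 rose and 2 fell, with Cd79b at -0.81. Ighm was at 856 ± 163 CPM in rat tail collagen and 955 ± 64.8 in media (-0.17, adjusted p = 0.276). Of the 4 measured red cell and platelet markers 1 rose and 1 fell. The red cell gene Alas2 had no counts in media and 1.44 ± 0.828 CPM in rat tail collagen, at least 67.4-fold higher. The platelet gene Itga2b was at -0.30 (adjusted p = 0.128). The B cell, stromal and red cell lists had fewer than 5 measured members and were not tested as lists.

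In all, 11319 of 19392 genes tested changed (58.4%), 5759 higher and 5560 lower, and of these 3108 were higher and 1334 lower by 2-fold or more. The 3 libraries of one group lay on one side of the other group's 3 in 64.8% of genes, where chance gives 10%. Camera called 9 of the 29 lists tested, and the calls of resident memory, lower, and of chemokine and S1P receptors held with an estimated correlation. Both of these lists hold S1pr1, S1pr4, S1pr5, Ccr7 and Cx3cr1, so their calls are not independent. Fry, which tests whether a list's genes move on balance one way, called 18 lists. Those that camera did not call were resident memory, higher, inhibitory receptors, immediate early genes, YAP and TAZ targets and mechanosensitive channels. The amino acid response, p53 targets and myeloid markers, all towards higher values, and cholesterol synthesis, towards lower values, were also among them. Adjusted over the list alone the counts were the same except for 19 higher in resident memory, higher, 4 lower in inhibitory receptors, 7 higher in YAP and TAZ targets, 6 lower in integrins, 14 lower in hypoxia, 4 higher and 8 lower in glycolysis, 9 lower in oxidative phosphorylation, 26 lower in S phase and 2 lower in red cell and platelet markers. Median and mean or test differed in sign for cytotoxic and effector molecules, IL-2 and STAT5 response, SRF and MRTF targets, integrins, NK, gamma-delta and CD4 T cell markers and, untested as a list, red cell and platelet markers, and camera and fry differed in direction for the T cell receptor response. Without the 3 libraries of highest rRNA share, chosen after the data were seen, 1 rat tail collagen library was left, 6726 genes changed and the calls of Itgae (-1.28, adjusted p = 0.0839), Ifng (-1.26, adjusted p = 0.0538), Gzmb (1.03, 0.160) and Piezo1 (0.31, 0.0701) were lost with fewer libraries. The Gzmb call was also lost with no filter (0.0736), without media 3 (0.0618) and without rat tail collagen 3 (0.0515), and Piezo1 turned to -0.38 with GC and length offsets (adjusted p = 4.68e-04). Lists that did not pass were called without single libraries: YAP and TAZ targets without media 3 (adjusted p = 0.0442) or rat tail collagen 1 (0.0321), cholesterol synthesis without media 2 (0.0461) or media 3 (0.0190), and hypoxia without media 3 (0.0111). Ighm passed without rat tail collagen 3 (-0.32, adjusted p = 0.0347) and Itga2b with GC and length offsets (-0.75, 0.00129).

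**Figure D3:**
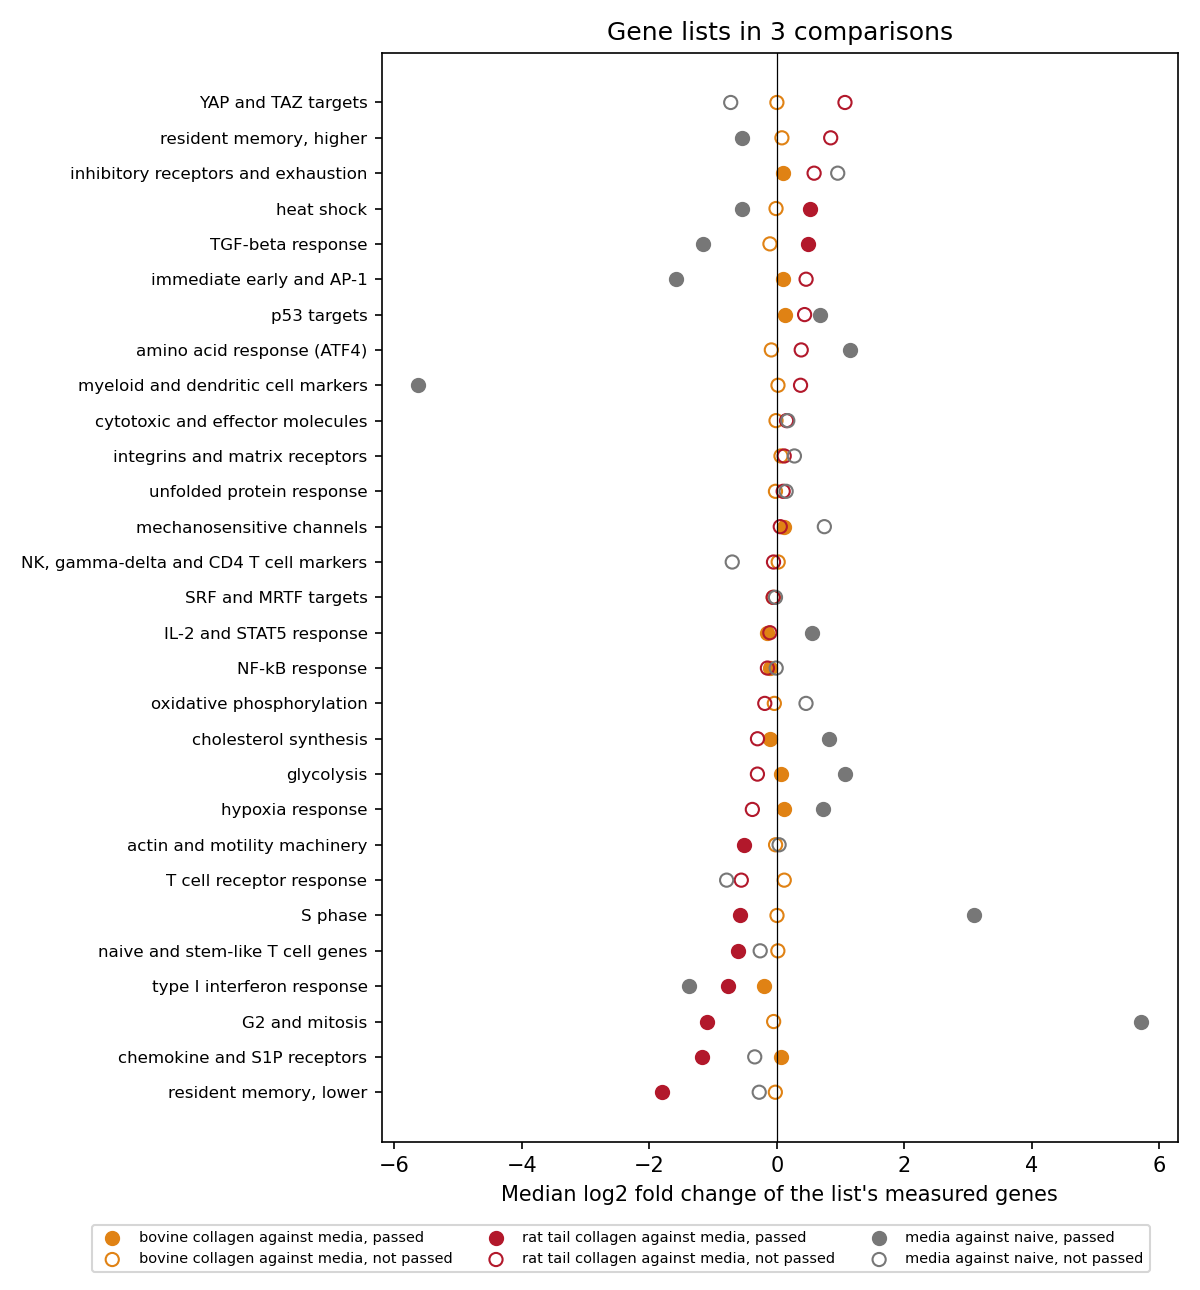
Median log2 fold change of the measured genes of each list tested in bovine collagen against media, rat tail collagen against media and media against naive cells, filled where camera with the preset correlation passed. The rat tail collagen medians of these lists run from -1.79 for resident memory, lower, to 1.07 for YAP and TAZ targets, which did not pass.

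Bovine collagen was compared with media to ask what a gel of another collagen source goes with at the same time and concentration. Few genes changed. Fosb, an immediate early gene that encodes an AP-1 subunit (GRCm38 chromosome 7, 19302696 to 19310051), rose 8.50-fold, from 2.53 ± 0.514 to 21.5 ± 3.76 CPM (log2 3.09, adjusted p = 4.28e-05). Fos, its paralog (chromosome 12, 85473890 to 85477273), rose 6.90-fold, from 0.977 ± 0.259 to 6.77 ± 1.15 CPM (log2 2.79, adjusted p = 9.78e-04). The transcription factor gene Klf4 (chromosome 4, 55527143 to 55532466) rose from 0.536 ± 0.157 to 2.48 ± 0.826 CPM (log2 2.21, adjusted p = 0.0277), and the uncharacterised Gm37352 (chromosome 8, 84200869 to 84203049) from 5.68 ± 0.940 to 15.5 ± 2.73 CPM (1.45, adjusted p = 0.00511). Klf4 and Gm37352 are named because the count is small, after their values were seen. All 4 were also higher in rat tail collagen than in media, Fosb by 1.65, Fos by 1.07, Klf4 by 4.46 and Gm37352 by 1.86, and of these the Fos call was lost without the 3 libraries of highest rRNA share, which leaves 1 rat tail collagen library (0.94, adjusted p = 0.0614). Naive cells, taken fresh, held Fos at 330.4 ± 117, Fosb at 174 ± 70.8 and Klf4 at 20.5 ± 4.74 CPM.

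None of the 12 residence and effector genes passed the test. Itgae was at 215 ± 90.9 CPM in bovine collagen and 227 ± 77.2 in media, Cxcr6 at 80.7 ± 4.61 and 81.0 ± 12.2, Cd69 at 89.4 ± 10.4 and 63.1 ± 9.50, and Piezo1 at 89.9 ± 3.26 and 84.2 ± 4.10. The log2 values of the others were 0.37 for Itga1, -0.41 for Zfp683, 0.19 for Klf2, 0.07 for S1pr1, 0.27 for Ccr7, 0.04 for Tcf7, 0.22 for Gzmb and -0.39 for Ifng. Nearest to the threshold were Cd24a, at 8.91 ± 2.17 against 4.51 ± 0.205 CPM (adjusted p = 0.0602), Tnf (-0.53, adjusted p = 0.0817) and Ctla4 (0.47, adjusted p = 0.0888), and Cd24a was picked after its value was seen. DESeq2 called Tnf (adjusted p = 3.45e-05) and Ctla4 (1.74e-06), no filter Tnf (4.55e-05), Ctla4 (0.00188) and Cd69 (0.00223), and library totals Tnf (0.0267). Osm was called lower by DESeq2 (7.10e-05), with library totals (0.00251) and with no filter (3.63e-09), Cish lower by DESeq2 (0.00268) and Cdkn1a higher with no filter (0.0365).

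With the preset correlation camera called 11 of 29 lists, 7 towards higher and 4 towards lower values, and with an estimated correlation it called none. Immediate early and AP-1 genes had Fos and Fosb of 22 members higher (median 0.10, adjusted p = 7.09e-11, and adjusted p = 0.0762 with an estimated correlation). In the other 10 lists no member passed over all genes. The p53 targets had a median of 0.14, with Cdkn1a at 0.42 and Phlda3 at 0.36 (adjusted p = 2.75e-05, and adjusted p = 0.0762 with an estimated correlation). Type I interferon genes had a median of -0.20, with Irf7 at -0.41 and Rtp4 at -0.64 (adjusted p = 2.45e-08, and adjusted p = 0.261 with an estimated correlation). IL-2 and STAT5 genes had -0.15, with Osm at -0.82 and Cish at -1.11 (adjusted p = 3.95e-07, and adjusted p = 0.224 with an estimated correlation). The remaining calls had an adjusted p of 0.00435 for hypoxia (Slc2a1 0.22, P4ha1 0.20), 0.00462 for chemokine and S1P receptors (Gpr183 0.39, Cxcr4 0.23), 0.0124 for mechanosensitive channels (Tmem63b 0.36, Trpv4 0.53), 0.0444 for inhibitory receptors (Ctla4, and Nr4a2 0.30) and 0.0444 for glycolysis (Slc2a1, and Slc2a3 0.30), all towards higher values. Towards lower values they were 0.00435 for cholesterol synthesis (Idi1 -0.25, Hmgcs1 -0.22) and 0.0170 for NF-kB (Tnf, and Nfkbia -0.22). In the same order their adjusted p with an estimated correlation was 0.886, 0.129, 0.224, 0.637, 0.951, 0.886 and 0.456. Leaving out a library ended 7 of these calls: chemokine receptors (without media 3, adjusted p = 0.0610), mechanosensitive channels (media 1, 0.183, bovine collagen 3, 0.105), cholesterol (media 1, 0.862, bovine collagen 3, 0.824), NF-kB (media 3, 0.260, bovine collagen 1, 0.114), hypoxia (media 3, 0.828, bovine collagen 1, 0.606, bovine collagen 2, 0.0803), inhibitory receptors and glycolysis. The inhibitory receptor call ended without media 2 (0.0724), media 3 (0.447), bovine collagen 1 (0.309) or bovine collagen 2 (0.0803), and that of glycolysis without media 2 (0.0773), media 3 (0.649, with the direction turned), bovine collagen 1 (0.978) or bovine collagen 2 (0.157). Library totals in place of TMM factors moved the median of all genes by -0.09, which is more than the medians of the glycolysis (0.07) and chemokine (0.07) lists. These medians therefore depend on the scaling. The camera calls compare a list with all other genes, and they were not run with library totals. With RLE factors camera called 11 lists too.

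In the lists that did not pass no member passed over all genes. Those of smallest adjusted p were Sik1 (0.21) beside Ctla4 and Cd69 in resident memory, higher, Ly6c1 (-0.37) beside Ccr7 in resident memory, lower, and Bcl2 (-0.39) beside Ccr7 among stem-like genes. Effector genes gave Nkg7 (0.17) beside Tnf, T cell receptor genes Tnf and Cd69 (0.50), TGF-beta genes Tgif1 (0.39) and Skil (-0.20), and YAP and TAZ targets Nuak2 (-0.51) and Ptpn14 (0.54). SRF and MRTF targets gave Srf (-0.19) and Mical2 (0.40), integrins Itga4 (0.21) and Itgav (0.16), and actin genes Lmna (0.54) and Cfl1 (-0.13). Oxidative phosphorylation gave Ndufc2 (-0.17) and Ndufa4 (-0.17), the amino acid response Nupr1 (-1.21) and Asns (-0.27), the unfolded protein response Herpud1 (-0.12) and Syvn1 (0.25), and heat shock Hspa1a (0.68) and Hspd1 (-0.14). S phase gave E2f1 (0.14) and Cdc45 (0.08), and G2 and mitosis Cdc20 (-0.19) and Aurka (-0.11). Markers of other cells gave Cd79a (-0.24) and Ighd (-0.08), Cst3 (-0.16) and Itgam (0.41), Cd40lg (0.39) and Cd4 (-0.26), Pdgfrb (0.78) and Pecam1 (-0.07), and Itga2b (0.25) and Ppbp (0.16).

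EdgeR called 4 of 19392 genes higher and 0 lower, with 810 genes at an unadjusted p under 0.05. DESeq2 called 14 higher and 7 lower, library totals gave 6 and 3, no filter 21 and 18, and limma-voom 3 and 0. The share of genes with all libraries of one group on one side was 8.78%, where chance gives 10%. Fry called none of the lists. Adjusted over the list alone, 2 further immediate early genes were called higher, Ctla4 in 2 lists, Cd69 in the T cell receptor list and 1 stromal marker were called higher, and Tnf in 3 lists, 3 IL-2 and STAT5 genes and 1 interferon gene were called lower. Median and mean or test differed in sign for stem-like genes, effector molecules, YAP and TAZ targets, SRF and MRTF targets, heat shock and myeloid markers. Without the 3 libraries of highest rRNA share, of which bovine collagen 2 is one, only Fosb was called, Fos stood at 2.65 (adjusted p = 0.130), and without media 2, Klf4 (adjusted p = 0.195) and Gm37352 (0.0631) were lost. The Klf4 call was also lost without media 3 (0.0720), without bovine collagen 2 (0.0926) and with limma-voom (0.105). With only the 6 libraries of the comparison Klf4 (2.21, adjusted p = 0.304) and Gm37352 (1.45, 0.0957) were lost. Lists that did not pass were called without single libraries too: oxidative phosphorylation without media 2 (adjusted p = 0.00530), media 3 (1.69e-04) or bovine collagen 1 (1.55e-05), TGF-beta without media 1 (0.0426) or bovine collagen 3 (0.0133), G2 and mitosis without media 1 (0.0314) or bovine collagen 3 (0.00200), integrins without media 2 (0.0466), the amino acid response (0.0314) and resident memory, higher (0.0301) without bovine collagen 1, and the T cell receptor response without bovine collagen 3 (0.0384).

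Rat tail collagen was compared with bovine collagen to test the difference between the gels itself. Ccr2 was at 3.21 ± 0.609 CPM in rat tail and 169 ± 13.0 in bovine collagen, 52.3-fold lower (log2 -5.71, adjusted p = 1.03e-09). Accsl had no counts in bovine collagen and 25.9 ± 7.62 CPM in rat tail collagen, at least 929-fold higher, and Prrg3 was at least 367-fold higher. With counting intervals, the ratio was 2372 (425 to 93703) for Chst1, 1817 (326 to 71806) for the NMDA receptor subunit gene Grin2c, 1636 (293 to 64666) for Tnn and 694 (237 to 3370.1) for the transcription factor gene Tal2. Stc1 was higher by log2 9.68 and Npr1 by 9.41. Lower were Ifi213 (-5.18), Cd7 (-4.71), Ifi206 (-4.33), Rap1gap2 (-4.29), Ifi208 (-4.28) and Anxa1, which encodes the phospholipid-binding annexin A1 (7.42 ± 1.34 to 0.415 ± 0.156 CPM). Of the residence and effector genes Itga1 (1.54), Gzmb (1.05) and Piezo1 (0.26) were higher in rat tail collagen. Lower were Itgae (-1.56), Cd69 (-1.47), Cxcr6 (-2.51), Zfp683 (-1.09), Klf2 (-2.62), S1pr1 (-1.83), Ccr7 (-0.46) and Ifng (-0.96). Tcf7 did not pass (-0.17, adjusted p = 0.288).

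Camera called 10 of 29 lists, 2 towards higher and 8 towards lower values in rat tail collagen. Resident memory, lower, had 16 of 19 members lower, with Ripor2 at -2.48 (adjusted p = 1.63e-21, and adjusted p = 0.0267 with an estimated correlation). Chemokine and S1P receptors had 11 of 14 lower, with S1pr4 at -2.15 and Gpr183 at -3.91 (adjusted p = 1.64e-12, and adjusted p = 0.00660 with an estimated correlation). These 2 calls held with an estimated correlation, and the other 8 did not. The 2 lists share members such as S1pr1 and S1pr4, so their calls are not independent. G2 and mitosis had all 30 members lower (Birc5 -1.35, Cdc20 -1.07), S phase 27 of 31 (Rrm2 -1.40, Tyms -1.09), the actin list 26 of 31 (Vim -2.43, with Rhob at 2.14) and stem-like genes 10 of 20 (Il7r -1.48). Heat shock genes were higher in 8 of 14 (Hspa1b 6.48, Hspa1a 6.22). For these 5 lists the adjusted p was 0.284 with an estimated correlation, and with the preset it was 1.71e-18, 3.12e-08, 4.36e-04, 9.15e-06 and 3.12e-08. TGF-beta genes were higher in 7 of 12 (Skil 1.72, Pmepa1 2.55, adjusted p = 0.0115, and adjusted p = 0.478 with an estimated correlation). Interferon genes were lower in 14 of 26 (Rtp4 -3.66, Ifit2 -1.13, adjusted p = 0.0119, and adjusted p = 0.834 with an estimated correlation). Hypoxia genes were lower in 14 of 24 (Pdk1 -2.45, with Pfkfb4 at 2.01, adjusted p = 0.0165, and adjusted p = 0.907 with an estimated correlation).

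The lists that did not pass held single genes that did. Skil and Nr4a2 (1.87) of resident memory, higher, Entpd1 (2.13) of the inhibitory receptors, Tnfrsf4 (2.65) of the T cell receptor response and Ier3 (2.26) of the immediate early genes were higher, and Cd160 (-2.48), Zfp36 (-1.99) and Nkg7 (-0.95) were lower, with Srgn at 0.90. Socs3 (1.66) and Cd83 (2.16) were higher, and Ccnd3 (-0.61) and Rel (-1.24) lower. Arhgef17 (3.15), Mical2 (4.19), Ddr1 (1.66) and Trpv4 (1.98) were higher, and Asap1 (-1.81), Flna (-1.08), Itga2 (-3.53) and Trpv2 (-0.63) lower. Among metabolic genes Hk1 (1.02) was higher, and Slc16a1 (-0.92), Uqcrfs1 (-0.67), Atp5c1 (-0.66), Ebp (-0.77) and Stard4 (-0.93) were lower. Chac1 (3.01), Atf5 (0.86), Xbp1 (1.15), Aen (1.03) and Cdkn1a (1.27) were higher and Dnajc3 (-0.70) lower. Markers of other cells included Col1a1 (3.68), Cd14 (3.62), Cd68 (1.66), Klrb1c (4.34) and Zbtb7b (0.93), which were higher, Cd79b (-0.84), Pecam1 (-0.90) and Itga2b (-0.55), which were lower, Ighm (-0.16, adjusted p = 0.311), and Alas2, with a ratio of 50.2 (16.9 to 246).

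In this comparison 10617 of 19392 genes changed, 5499 higher and 5118 lower, and 2963 and 1209 of them by 2-fold or more. The share of genes with all libraries of one group on one side was 63.8%, where chance gives 10%. Adjusted over the list alone the counts differed in resident memory, higher (10 lower), stem-like genes (4 higher), T cell receptor response (9 lower), interferon (6 higher and 16 lower), SRF and MRTF targets (5 higher) and B cell markers (2 lower), and fry called 16 lists. Median and mean or test differed in sign for effector molecules, immediate early genes, NF-kB, SRF and MRTF targets, integrins, mechanosensitive channels, and NK, gamma-delta and CD4 T cell markers. Library totals in place of TMM factors moved the median log2 change of all genes by 0.144 and the share of changed genes that were higher from 51.8% to 66.3%, and the Ccr7 call was lost (adjusted p = 0.0532). Without the 3 libraries of highest rRNA share 1 rat tail collagen library was left, 5485 genes changed, and Itgae (-1.31, adjusted p = 0.0996), Zfp683 (-0.93, 0.0991), Gzmb (0.85, 0.296), Ifng (-0.996, 0.136) and Piezo1 (0.25, 0.170) did not pass with fewer libraries. Piezo1 turned to -0.37 with GC and length offsets. Single libraries ended the calls of Gzmb (without bovine collagen 2, adjusted p = 0.0789, bovine collagen 3, 0.0643, rat tail collagen 1, 0.0643, or rat tail collagen 3, 0.111), Ifng (bovine collagen 1, 0.121, rat tail collagen 2, 0.0547, or rat tail collagen 3, 0.0785), Piezo1 (bovine collagen 3, 0.0669, or rat tail collagen 3, 0.0735) and Itga2b (rat tail collagen 1, 0.0505). Itga2b was also lost with library totals (-0.40, adjusted p = 0.127) and with all libraries in one fit (-0.54, 0.124), Gzmb and Piezo1 with no filter (0.140 and 0.0540), and Zbtb7b (0.42, 0.0668) and Ifng (-0.70, 0.0764) with GC and length offsets. With fewer libraries, without the 3 of highest rRNA share, Ccr7 (-0.47, 0.0586), Zbtb7b (0.94, 0.0634) and Itga2b (-0.42, 0.265) were lost, and with only the 6 libraries Gzmb (0.0547). Ighm passed without rat tail collagen 3 (0.0401). Calls were gained by YAP and TAZ targets without bovine collagen 3 (0.0426) or rat tail collagen 1 (0.0208), the amino acid response without bovine collagen 1 (0.0382), rat tail collagen 1 (0.0210) or rat tail collagen 2 (0.0196) and cholesterol synthesis without bovine collagen 3 (0.0232).

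The genes called higher in both collagens against media numbered 4, Fosb, Fos, Klf4 and Gm37352, and lists of these sizes drawn independently would share 1.19. No gene was lower in both. Both comparisons use the same media libraries, which were too few to divide between them. In 20 simulated sets of unchanged groups that shared their media libraries, the highest shared count was 0. Those sets held no true change in either collagen, whereas 11319 genes were called in rat tail collagen here. They therefore give no null for the 4 shared genes or for the correlation of fold changes. Across the 19392 genes, which are not independent replicates, the fold changes of the comparisons had a correlation of 0.245 and a covariance of 0.122, against a mean correlation of 0.473 and a mean covariance of 0.0258 in the simulated sets. Fosb and Fos were higher in bovine than in rat tail collagen (-1.44 and -1.71 for rat tail against bovine), and Klf4 was higher in rat tail collagen (2.26). Gm37352 was at 0.41 (adjusted p = 0.0270), a call that was lost without bovine collagen 1 (0.106), without bovine collagen 2 (0.0989), without rat tail collagen 1 (0.0867), without rat tail collagen 2 (0.0681) and with all libraries in one fit (0.0989), and the value turned to -0.0690 with GC and length offsets.

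Media cells of day 4 were compared with naive cells of day 0 to show how the control cells of the gels differed from naive cells. Naive cells were lysed fresh, while media cells were activated, expanded and cultured. Activation, time in culture and handling therefore cannot be told apart in this comparison. Cell cycle genes rose together. All 30 genes of G2 and mitosis rose, with a median of 5.72, led by Nusap1, a spindle protein gene, from 3.55 ± 0.236 to 272 ± 9.23 CPM (6.32), and Kif20a (5.34). Of the S phase genes 30 of 31 rose, with Rrm2 at 5.84 and Cdc45 at 4.22. These lists had an adjusted p of 2.37e-147 and 7.77e-65, and their calls held with an estimated correlation (adjusted p = 0.0187 and 0.0119). The 8 largest rises also held Gucy2e, a guanylyl cyclase gene (chromosome 11, 69218117 to 69237036), from 0.190 ± 0.0849 to 66.1 ± 10.3 CPM (log2 8.51), the protease inhibitor gene Serpine2 (7.29), Tnfrsf8, which encodes CD30 (6.63), and the cell cycle genes Pimreg (6.73), Ska1 (6.71), Pclaf (6.45) and Esco2 (6.32). Gzmb rose from 5.19 ± 1.45 to 376 ± 135 CPM (6.24), and Il2ra, a chain of the interleukin 2 receptor, by 5.46.

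Among the largest falls were 3 HSP70 genes. Hspa1a went from 1014 ± 398 to 0.452 ± 0.0447 CPM and Hspa1b from 1244 ± 479.7 to 0.758 ± 0.117, and Hspa1l had no counts in media, at least 1177-fold lower. Of the heat shock list 9 of 14 fell and 3 rose (adjusted p = 3.14e-04, and adjusted p = 0.522 with an estimated correlation). Immediate early and AP-1 genes fell in 19 of 22, with Fosl2 at -2.29 and Ier5 at -2.10 (adjusted p = 2.03e-11, and adjusted p = 0.374 with an estimated correlation). Type I interferon genes fell in 20 of 27, with Oas2 at -3.98 and Oasl2 at -4.35 (adjusted p = 3.36e-06, and adjusted p = 0.522 with an estimated correlation). TGF-beta genes fell in 10 of 12, with Smurf2 at -1.64 and Ski at -1.63 (adjusted p = 3.14e-04, and adjusted p = 0.374 with an estimated correlation). Resident memory, higher, had 18 of 31 lower and 8 higher, with Rgs2 at -4.70 and the inhibitory receptor gene Ctla4 at 4.90 (adjusted p = 0.0238, and adjusted p = 0.374 with an estimated correlation).

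Metabolic genes rose. Cholesterol synthesis genes rose in 23 of 24, with Stard4 at 1.89 and Sqle at 2.63, glycolysis genes in 14 of 17, with Slc16a3 at 4.46 and Pgk1 at 2.31, and hypoxia genes in 17 of 24, with Bnip3 at 3.17 and Egln3 at 3.47. The adjusted p of these 3 lists was 2.12e-06, 3.14e-04 and 0.0278, and the adjusted p was 0.577, 0.626 and 0.711 with an estimated correlation. Amino acid response genes rose in 12 of 19 (Trib3 4.34, Asns 5.57), p53 targets in 12 of 17 (Cdkn1a 4.34, Ccng1 1.43) and IL-2 and STAT5 genes in 8 of 13 (Socs2 3.98). The adjusted p of these 3 lists was 0.00873, 0.0238 and 0.0400, and the adjusted p was 0.577, 0.374 and 0.392 with an estimated correlation. The IL-2 and STAT5 call was lost without naive 2 (adjusted p = 0.0522).

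Myeloid and dendritic cell markers were higher in the naive libraries, and the B cell, NK and red cell lists did not pass. Of the myeloid and dendritic markers 10 of 14 were lower in media, with Flt3 at -4.86 and Tyrobp at -3.73 (adjusted p = 0.0238, and adjusted p = 0.711 with an estimated correlation). The macrophage genes Sirpa, Mrc1, C1qc, C1qb and C1qa had no counts in media and were at least 516, 391, 312, 270.4 and 254-fold lower. Most of their counts came from naive 1, where C1qa was at 12.9 CPM against 1.65 and 2.00 in the other naive libraries. Of the B cell markers 7 of 11 were lower and Ighm was higher (1.16), and the ratio of naive to media for Pax5 was 43.4 (14.4 to 213). The NK, gamma-delta and CD4 list had 6 of 13 lower, with Ncr1 at -7.64 and Ikzf2 at 2.22. Of stromal markers Fn1 was at -6.13 and Col1a1 at -1.02. Of red cell and platelet markers Gp9 was at -3.06 and Hba-a2 at -3.70.

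The lists left did not pass. Of the residence and effector genes Cd69 (-1.51), Cxcr6 (-0.42), Itga1 (-1.44), Zfp683 (-0.86), Klf2 (-1.42), S1pr1 (-0.27), Ifng (-1.63) and Piezo1 (-0.49) were lower in media. Itgae (-0.13), Ccr7 (-0.10) and Tcf7 (0.20) did not pass, though Itgae passed without media 3 (-0.43, adjusted p = 0.0104) and Tcf7 with GC and length offsets (0.27, 0.0443). Rap1gap2 (2.27), Myb (1.75), Klrd1 (1.89), Tnf (1.30), Tigit (3.71), Irf4 (3.61) and Nfkb1 (0.92) were higher, and Sidt1 (-1.27), Igfbp4 (-2.96), Prf1, which encodes perforin (-3.69), Tox (-2.98), Egr3 (-3.67) and Tnfaip3 (-1.51) were lower. The S1P receptor gene S1pr5 had no counts in media and was at least 143-fold lower, while the chemokine receptor gene Cxcr3 (1.79) was higher. Among genes of mechanics Vcl (2.28), Actg1 (0.81), Itgb3 (2.11), Itgb1 (1.29), Vim (1.81), Kcnk6 (2.27) and Trpv2 (0.75) were higher, and Crim1 (-0.85), Gadd45a (-2.12) and Rhob (-2.81) were lower. Of the other lists Ndufc2 (1.18), Sdhb (0.90) and Sdf2l1 (1.83) were higher and Dnajb9 (-1.58) lower.

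In this comparison 11324 of 18610 genes changed, 5889 higher and 5435 lower, and 2830 and 2210 of them by 2-fold or more. The share of genes with all libraries of one group on one side was 67.6%, where chance gives 10%. Camera called 14 of 31 lists, 8 towards higher and 6 towards lower values, and fry called 25. Adjusted over the list alone the counts differed in resident memory, lower (6 higher), stem-like genes (3 higher and 12 lower), IL-2 and STAT5 (9 higher), NF-kB (7 higher), oxidative phosphorylation (24 higher), unfolded protein response (8 higher), S phase (1 lower) and myeloid markers (2 higher). Median and mean or test differed in sign for SRF and MRTF targets and the unfolded protein response. The calls of Sirpa, Mrc1, C1qc, C1qb and C1qa were lost with no filter (adjusted p from 0.149 for Sirpa to 0.194 for C1qa), without media 1 (from 0.0904 for C1qb to 0.121 for C1qa), without media 3 and with GC and length offsets (from 0.0506 for C1qb to 0.0713 for C1qa), and those of Sirpa (0.0774) and Mrc1 (0.0687) also without naive 2. Without media 2 the calls of Cxcr6 (adjusted p = 0.0599) and S1pr1 (0.0798) were lost, and without media 1 that of the myeloid list (0.0504). Calls were gained by oxidative phosphorylation without naive 3 (0.0281), media 2 (0.0359) or media 3 (0.0199), inhibitory receptors without naive 1 (0.0369) or media 3 (0.0194) and B cell markers without naive 3 (0.0261), and the Col1a1 call was lost with DESeq2 (-1.04, adjusted p = 0.0605).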

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

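The tests of tendon RNA, of a general heat shock response and of handling were chosen only after the result was seen, as were the first 11 tonicity genes, and the GC and length offsets were added after the data were seen.

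Each result in this paragraph was picked out because rat tail and bovine collagen differed from each other in the direct test. In all, 10617 genes differed. On the log2 scale, rat tail minus bovine, the fitted changes were 13.05 for Accsl, 11.70 for Prrg3, 10.72 for Chst1, 10.27 for Grin2c, 10.18 for Tnn, 9.68 for Stc1, 9.41 for Npr1 and 9.19 for Tal2. Fits of Accsl, Prrg3, Chst1, Grin2c, Tnn and Tal2 rest on 0 to 3 counts over the bovine collagen libraries, depend on the prior count and bound no fold. Lower were Ccr2 (-5.71), Ifi213 (-5.18), Cd7 (-4.71), Ifi206 (-4.33), Rap1gap2 (-4.29), Ifi208 (-4.28) and Anxa1 (-4.09). Residence and effector genes were at -1.56 for Itgae, -1.47 for Cd69, -2.51 for Cxcr6, 1.54 for Itga1, -1.09 for Zfp683, -2.62 for Klf2, -1.83 for S1pr1, -0.46 for Ccr7, 1.05 for Gzmb, -0.96 for Ifng and 0.26 for Piezo1. Genes called in bovine collagen were at -1.44 for Fosb, -1.71 for Fos, 0.41 for Gm37352 and 2.26 for Klf4. List medians were -1.93 for resident memory, lower, -0.35 for stem-like genes, 0.56 for TGF-beta, -0.63 for interferon, -0.47 for actin and motility, -1.19 for chemokine and S1P receptors, -0.51 for hypoxia, 0.58 for heat shock, -0.58 for S phase and -1.03 for G2 and mitosis.

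The first pattern is that rat tail collagen differed from media in 11319 genes, while rRNA held 10.96%, 5.03% and 13.2% of counts in its libraries and 4.45% to 4.72% in media. Residual rRNA as the whole cause is argued against by 8129 genes called with the rRNA share as a covariate, 8068 of them among the 11319 and in the same direction, while 9 genes were called for the share itself. GC content and length are argued against as the whole cause by 11435 genes called with offsets for them, 9395 of them among the 11319 and in the same direction, and RNA of rat tail tendon cells by a median of 0.0690 CPM of the 5 tendon transcripts Col1a1, Col1a2, Col3a1, Dcn and Sparc in rat tail collagen, with Col1a1 highest at 4.29 ± 0.535 CPM. Rat reads that do not align to the mouse genome would be missed. Left open are RNA degradation and a different share of dying cells, of which the labels give no measure, and a response of the cells to the rat tail gel or its mechanics, which may be the cause and was not tested.

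The second pattern is that genes known to respond to hypertonic medium rose in rat tail collagen. Of 11 genes picked after their values were seen all rose, with a median of 3.29, among them the myo-inositol transporter gene Slc5a3 (18.5 ± 2.33 to 403 ± 71.7 CPM), the aldose reductase gene Akr1b3 (43.0 ± 5.83 to 760.1 ± 227) and the tonicity-responsive transcription factor gene Nfat5 (76.6 ± 12.1 to 612 ± 31.2). Over the other scalings the lowest median of these genes was 3.31. RLE factors and library totals moved the median of all genes by only 0.0223 and 0.0558. A rise of this size could therefore hardly have been lost, and the check shows only that the choice among these scalings matters little here. A general heat shock response stays open: 7 HSF1 targets had a median of -0.20, but they were chosen after the result was seen and leave out 7 heat shock genes that rose, among them Hspa1a, Hspa1b and Hsph1. A list of 10 other tonicity genes, of which 7 were measured, was written before its values were seen and had a median at percentile 99.85 of random lists matched on expression in rat tail collagen, so a hypertonic gel may be a candidate explanation. The same list lay at percentile 99.98 in bovine collagen, where its median was 0.15 and no member was called, so the percentile does not separate the gels, and osmolality, pH and salt of the gels stay open.

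The third pattern is that the immediate early genes Fosb and Fos, with Klf4, rose in bovine collagen (adjusted p = 4.28e-05, 9.78e-04 and 0.0277). A single deviating bovine library is argued against for Fosb and Fos by their highest adjusted p of 0.00770 without 1 bovine library, while Klf4 kept its size and lost its call with 1 library fewer, without bovine collagen 2 (2.28 against 2.21, adjusted p = 0.0926, range over the alternatives 3.72e-18 to 0.769). Without the 3 libraries of highest rRNA share Fos did not pass either (2.65 against 2.79, adjusted p = 0.130, range 1.12e-32 to 0.130). Handling during recovery of cells from gels could not be told apart from a response to collagen, since 3 of the 3 genes Fos, Fosb and Klf4 were higher in rat tail collagen too, and per the labels only cells in gels were recovered from gels. A response to collagen stays open and was not tested.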

How the results depend on the processing

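The rRNA, GC and length alternatives were chosen after the data were seen, and where no construction is named the cause was not tested. Counts of changed genes were 11319 (rat tail collagen against media), 10617 (rat tail against bovine collagen) and 11324 (media against naive). They kept within 1.5 times of these values under the scalings, tools, filters and sample sets tried, with the following exceptions. A 2-fold minimum gave 4442, 4172 and 5040, which follows from construction. Without the 3 libraries of highest rRNA share, which leaves 1 rat tail collagen library, the counts of the first and second comparison were 6726 and 5485. Whether this fall came from fewer libraries or from removing high rRNA shares cannot be told, since no other 3 libraries were left out. Leaving out a library gave 9986 to 11137, 9346 to 10091 and 10136 to 11310. For bovine collagen against media (4) the count was 9 with library totals, 21 with DESeq2, 39 with no filter, 7 with the replicate block, 2 with only its 6 libraries, 1 without the 3 libraries and 2 to 5 without a library. With the replicate block the other counts were 12070, 11402 and 10407, and the labels do not say that equal numbers pair samples. Of 18 pairs of equal number 5 had a residual correlation over 0.1, over a range from -0.0254 to 0.444. In 25 of 36 checks a library correlated best with its own number in another group, where chance gives 12. Between media and bovine collagen the correlation was 0.373 for number 1, 0.0290 for number 2 and 0.444 for number 3. There the own number was best in 5 of 6 checks. This is a hint from the data and not the design, and the main fit of bovine collagen against media leaves it out. Lists called, in the order rat tail against media, bovine against media, rat tail against bovine and media against naive, went from 9, 11, 10 and 14 to 2, 0, 2 and 2 with an estimated correlation, and to 18, 0, 16 and 25 with fry, which tests another question. The replicate block gave 10, 13, 10 and 16. The bovine lists numbered 5 without the 3 libraries and 7 to 12 without a library. Genes changed in both collagens (4) numbered 15 with DESeq2, 31 with no filter, 1 without the 3 libraries and 2 to 5 without a library. The first component held 55.2% of variance over all genes and 62.2% over the 500 most variable. With GC and length offsets Piezo1 turned to -0.38 against media and -0.37 against bovine collagen, and Gm37352 to -0.0690 in rat tail against bovine collagen. The bovine glycolysis list turned direction without media 3 (adjusted p = 0.649), did not pass without media 2, bovine collagen 1 or bovine collagen 2 (0.0773, 0.978 and 0.157) and passed without media 1 (1.08e-06) or bovine collagen 3, with a range from 1.08e-06 to 0.996 over all alternatives. Of the values of named genes under the alternatives 2745, 2371, 2720 and 2528 in the same order of comparisons kept direction and side of the threshold, 30, 10, 55 and 26 fell below it and 11, 15, 8 and 6 passed it. For lists these were 376, 342, 385 and 365, then 12, 47, 8 and 17, then 18, 16, 13 and 20.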

Other observations

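The first 11 tonicity genes were chosen after their values were seen, and so was the test of a general heat shock response.

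Genes of osmolyte transport and volume control moved in rat tail collagen against media beyond the lists of the comparisons. Besides Slc6a12, which imports betaine, the taurine transporter gene Slc6a6 rose (1.07), the amino acid transporter gene Slc38a2 rose from 242 ± 15.8 to 521 ± 30.3 CPM (1.09) and the kinase gene Sgk1 from 42.9 ± 3.35 to 74.4 ± 11.7 (0.78). Cd24a, a surface glycoprotein gene, rose from 4.51 ± 0.205 to 175 ± 5.39 CPM (5.27) and S100a4 from 18.4 ± 8.46 to 86.9 ± 18.6 (2.23). Hspa4l, a chaperone gene of the HSP110 family, rose from 32.7 ± 0.910 to 321 ± 55.1 CPM (3.29). Of the genes not looked at before Pnpla6 (1.68), the cotransporter gene Slc12a2 (1.12), Gdpd5 (0.88) and the kinase genes Stk39 (0.67) and Wnk1 (0.53) rose. Atp1b1 did not pass (0.05, adjusted p = 0.937), and Ccl2, Lcn2 and Aqp5 did not pass the filter. In bovine collagen the 11 genes picked first had a median of 0.18 and none was called. Slc5a3 shares its strand and span with Mrps6, so its value is uncertain.

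A hypothesis from these values is that the rat tail gel may have been hypertonic to the cells. Its test, set before the values of the 10 further genes were seen, put their median at percentile 99.85 of random lists in rat tail collagen. Against it as a cause particular to that gel, the same genes lay at percentile 99.98 in bovine collagen with a median of 0.15. Their changes differed between the gels in size, with a median of 0.69 in rat tail against bovine collagen, where 5 rose and 1 fell. A measurement of osmolality in both gels would decide it.

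The libraries of each comparison were also split in all 10 ways that put 3 against 3, the real one included, which is too few for a share under 0.05. For rat tail collagen against media 1 split reached the real count of 11319 genes and the highest other gave 0, and for lists 9 splits reached the real 9 and the highest other gave 15. For rat tail against bovine collagen these were 1 split, 10617 and 0 for genes and 7 splits, 10 and 15 for lists. For media against naive they were 1 split, 11324 and 0 for genes and 2 splits, 14 and 14 for lists. For bovine collagen against media they were 2 splits, 4 and 205 for genes and 2 splits, 11 and 13 for lists. The split with 205 genes put bovine collagen 1, bovine collagen 2 and media 1 against the other 3 libraries, so these libraries also differ along something other than their groups. It kept both libraries of number 1 on one side and both of number 3 on the other, and divided those of number 2. Whether the replicate number marks this difference was not tested.

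For the 4 genes changed in both collagens, 98 splits of the 9 day 4 libraries into 3 groups of 3 were tested, the real one included. In 3 of them, the real one included, as many genes were shared. The highest other count was 9991, and both larger counts came from splits that took the 3 rat tail collagen libraries as the shared control. The other 95 splits shared 0 genes. Nearly all of them mixed rat tail collagen libraries with media or bovine collagen libraries. Mixed splits of rat tail collagen against media gave 0 genes, so such splits could hardly share any. The splits therefore give no null for the 4 shared genes.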
